A study of Mus musculus with 9 samples.

How the data were processed

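Bulk RNA sequencing was done on the substantia nigra pars compacta of mice in 3 groups of 3 libraries. Per the labels, RNA was extracted with an RNeasy column kit and libraries were made with the NEBNext Ultra RNA kit. The authors deposited 1 table that held, per the file headers, a raw read count and an FPKM value (fragments per kilobase of transcript and M mapped fragments, M being the SI prefix mega) for each gene in each library. The genome build was mm10 (GRCm38), per the submitters' processing notes. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here. Without a stated strand, reads of overlapping or antisense genes cannot be separated, and reads of near-identical copies such as Hspa1a and Hspa1b, the haemoglobin genes and the histone gene Hist2h2aa2 may be exchanged.

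The table held 27339 genes, of which 22036 carried an Ensembl identifier and 5303 an identifier of the authors' own for unannotated transcription. Of the Ensembl identifiers 22022 matched GENCODE M21 on GRCm38, which supplied the coordinates, and 21914 (99.5%) of them were protein coding. A further 10 lines named no gene and were not used, and 27 symbols had been turned into dates and were replaced through their identifiers. No column of an unmapped sample was present. Every library was mapped to its group by its title. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom within a group being 11.77.

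The design foresaw limma on log2 FPKM, and edgeR on counts if the table held raw counts. It did, so the second course was taken. Counts were tested with edgeR 4.0.16 (quasi-likelihood, robust, TMM scaling) in R 4.3.3, with all 9 libraries in 1 model so that the groups shared an estimate of the spread. Genes with a mean FPKM of at least 0.5 were tested, 14949 in all (13810 annotated, 1139 unannotated). The 12390 genes left out held 0.189% to 0.244% of the counts of a library. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05. CPM values use library sizes scaled by TMM, whose factors lay between 0.9833 and 1.016. The common biological coefficient of variation was 0.134.

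Gene lists, 44 in number, were fixed with the groups, the tests, most other settings and the rule for named genes before the data were examined. They cover cell types, brain regions, metabolism and stress responses. Each was tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. No list passed in any comparison with an estimated correlation, and none by fry in a shared direction. Whether replicate numbers pair the libraries was judged from the data alone, by the correlation of same-numbered libraries in their deviations from the group means, with a minimum of 0.1 for every pair. Between MPTP and the diet group the 3 pairs correlated at 0.107 to 0.182, which met this minimum. The main fits used no block, and a block by number is given beside a result of that comparison where it changed the call. Between Ctrl and MPTP the pairs correlated at -0.151 to 0.0472 and between Ctrl and the diet group at -0.00735 to 0.0783, below the minimum. Differently numbered libraries of different groups correlated at -0.168 to 0.186, so values of this size also arose without a shared number. A list score is the mean log2 level of its members with the mean of Ctrl set to 0, compared by exact permutation.

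Genes were named by rule. Per comparison these were the 10 genes of smallest p in each direction past the threshold, filled where fewer passed by the smallest unadjusted p among genes with a mean FPKM of at least 1 and an approved symbol. Up to 4 members of each list described were added, and always Th, Slc6a3, Slc18a2, Ddc, Gfap, Aif1, Bdh1 and Oxct1, and the genes of the sample checks. Members that passed adjusted over the list alone are named with their list, apart from some genes that the rules take and that are not reported here. Any gene outside the rule is said to have been chosen after its values were seen.

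Count and FPKM should give the same transcript length for a gene in every library. Among 12482 tested genes with at least 100 counts in every library, the median ratio of the highest to the lowest implied length was 1.02. The ratio exceeded 1.1 for 1946 genes (15.6%), 1.5 for 130 (1.04%) and 3 for 8 (0.0641%). For Dnajb1, Hspa1b, Hspa1a, Fos, Th and Slc6a3 it was 1, for Ddc 1.02 and for Hspa5 1.08.

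The tests were checked on simulated counts with the means, library sizes and spread of these data. Each simulation changed 212 genes. For MPTP against Ctrl, over 14949 genes and 5 simulations, edgeR called 61.2% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 93.3% of those changed 3-fold. Of its calls 6.20% were false, against 4.84% for limma and, in 1 simulation, 13.6% for DESeq2. For the diet group against MPTP edgeR called 57.0%, 78.5% and 92.1%, with 7.10% false, and for the diet group against Ctrl 59.7%, 77.0% and 90.9%, with 6.36% false. Where fewer genes change, the adjusted threshold is harder to pass and smaller shares would be called. The shares called therefore do not show how many changed genes would be found in the real libraries. A list changed 1.2-fold was called in 5 of 5 simulations, and 0 of 215 unchanged lists were called in each comparison. The simulated genes varied independently of each other. The list counts therefore do not show how often camera calls an unchanged list whose members vary together.

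Other settings fixed at that time were other pseudocounts on log2 FPKM, no filter or a filter at a mean FPKM of 1, median-ratio and quantile scaling, the replicate number as a block, array weights, no robust moderation, only the 6 libraries compared, other thresholds and each library left out in turn. DESeq2 1.42.0, limma on log2 FPKM with a pseudocount of 0.5, annotated genes only, the removal of both Ctrl 3 and MPTP 1, a replicate block in MPTP and the diet group only, and the choroid plexus, meningeal and serotonin neuron scores as covariates were added after seeing the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.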

Results

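RNA sequencing measured gene expression in the substantia nigra pars compacta of mice, the midbrain nucleus whose dopamine neurons project to the striatum. The 9 libraries fell into 3 groups of 3. The groups were controls (Ctrl), mice given MPTP, and mice given MPTP together with a ketogenic diet rich in medium-chain triglycerides (MPTP_MCTKD, called the diet group below). MPTP is a neurotoxin whose oxidised product enters dopamine neurons through the dopamine transporter and blocks mitochondrial complex I. A ketogenic diet replaces most carbohydrate with fat, so that the liver supplies ketone bodies as fuel. A group given the diet without MPTP was not analysed here, so the diet was measured only in mice that also received MPTP.

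Total counts per library ranged from 33.2 to 40 M (the SI prefix mega), with means of 37.7 ± 2.88 M in Ctrl, 34.8 ± 1.43 M in MPTP and 34.7 ± 0.844 M in the diet group (SD, n = 3). Mitochondrially encoded transcripts took 6.14% to 7.06% of the counts in a library. The Y-linked gene Ddx3y lay between 65.2 and 85.4 CPM (counts per M counts of a library) in all 9 libraries. Libraries of the same group correlated at 0.9823 to 0.9868 across genes, and libraries of different groups at 0.9776 to 0.9867. Genes are not independent replicates in these correlations. The labels do not say that each library came from its own animal, so the p-values measure the spread between these libraries.

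Markers of neighbouring tissue differed between libraries of the same group. Ttr, the main secreted protein of the choroid plexus, stood at 1060 CPM in the library Ctrl 3 and at 2.17 to 69.4 CPM in the other libraries. The pineal genes Tph1 and Crx reached 48.8 and 15.4 CPM in Ctrl 3. Tph2, the enzyme of serotonin synthesis in raphe neurons, was at 10.6 CPM in MPTP 1 and 14.0 CPM in diet library 1, against 26.6 to 102 CPM elsewhere. The mean log2 level of 12 meningeal fibroblast genes, set to 0 in Ctrl and listed after the data were seen, was -0.80 in Ctrl 3, -1.56 in MPTP 1, -1.17 in MPTP 2 and -1.45 in diet library 1. It lay between 0.099 and 0.72 in the remaining libraries. Ptgds, an abundant transcript of the meninges and of oligodendrocytes, was at 318 to 376 CPM in those 4 libraries and at 561 to 1090 CPM in the others.

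The comparison of MPTP with Ctrl addressed what the toxin changed in the nigra. Dnajb1, a heat-shock protein that guides Hsp70 to its substrates, fell from 88.4 ± 3.55 CPM in Ctrl to 60.3 ± 1.67 CPM in MPTP (SD, n = 3), and the inducible Hsp70 gene Hspa1b fell from 19.2 ± 3.12 to 8.17 ± 0.965 CPM. Dopamine neuron markers fell as a list, with a median 22.7% below Ctrl, and the Hsp70 and co-chaperone genes and the immediate early genes fell as lists with them (adjusted p = 0.241 with an estimated correlation for each of the 3 lists). Genes of the integrated stress and unfolded protein responses fell as a list too (adjusted p = 0.536 with an estimated correlation), and myelin genes of oligodendrocytes rose as a list by a median of 13.3% (adjusted p = 0.654 with an estimated correlation). Inflammatory, interferon and ketone metabolism genes did not pass the test as lists.

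Of 14949 genes tested, edgeR's quasi-likelihood test called 2, both lower in MPTP. Dnajb1 (ENSMUSG00000005483, chromosome 8, 83608193 to 83612653, GRCm38) had a log2 fold change of -0.55 (SE 0.0652, adjusted p = 0.0141). Hspa1b (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238) had a log2 fold change of -1.23 (SE 0.167, adjusted p = 0.0417). All 3 MPTP libraries lay below all 3 Ctrl libraries for both genes. Hspa1b has a near-identical copy, Hspa1a (chromosome 17, 34969190 to 34972156), whose reads the counting could exchange with it. Hspa1a stood at 13.1 ± 1.88 CPM in MPTP and 19.6 ± 2.80 CPM in Ctrl (log2 fold change -0.59, adjusted p = 0.893), so the split between the copies is uncertain. At an unadjusted p under 0.05 there were 400 genes higher and 402 lower. Expression did not overlap between the groups for 1576 genes (10.5%, where chance gives 10%). DESeq2 called 14 genes and limma on log2 FPKM called 0, with 850 under an unadjusted p of 0.05.

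The calls were often lost when 1 library was left out, although both genes stayed lower in MPTP. Dnajb1 lost its call without Ctrl 2, Ctrl 3, MPTP 2 or MPTP 3 (adjusted p = 0.0689, 0.158, 0.0585 and 0.104), while its log2 fold change stayed between -0.53 and -0.58. Hspa1b kept its call only without diet library 1 or 2, and without each of the others its adjusted p ranged from 0.0689 to 0.293 and its log2 fold change from -1.10 to -1.33. Neither gene passed without robust moderation (adjusted p = 0.0545 and 0.137), with limma on log2 FPKM (0.0929 and 0.183) or with the choroid plexus score as a covariate (0.0883 and 0.117), and Hspa1b did not with the meningeal or the serotonin neuron score (0.0580 and 0.109). With Ctrl 3 and MPTP 1 both left out the adjusted p was 0.351 for Dnajb1 and 0.584 for Hspa1b. The covariates and the removal of both libraries were chosen after seeing the data. Other genes passed with some libraries left out: Fsd1l without MPTP 2, Hist2h2aa2 without MPTP 1, and Hspa5 and Fos without diet library 1, where 4 genes were called.

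Other genes at the low end of the p-values did not pass and are given as values. Hspa5, the main chaperone of the endoplasmic reticulum, was at 270 ± 7.83 CPM in MPTP and 352 ± 10.1 CPM in Ctrl (adjusted p = 0.172). The small heat-shock gene Hspb1 was at 10.7 ± 1.18 and 16.9 ± 1.29 CPM (adjusted p = 0.250), and the myo-inositol transporter gene Slc5a3 at 61.8 ± 2.93 and 79.6 ± 3.45 CPM (adjusted p = 0.208). The log2 fold changes of Dnajb4 and Vegfa were -0.31 and -0.29 (adjusted p = 0.349 for both). Those of the collagen chaperone gene Serpinh1 and the prolyl hydroxylase gene P4ha1 were -0.58 and -0.30 (adjusted p = 0.393 for both). Fos was at 8.94 ± 1.03 CPM in MPTP and 19.2 ± 4.25 CPM in Ctrl (adjusted p = 0.405). Among the genes higher in MPTP, the Wnt receptor gene Fzd6 had a log2 fold change of 0.51 (adjusted p = 0.397). Prox1, Kndc1, Srsf5 and Chadl had log2 fold changes of 0.33, 0.22, 0.26 and 0.36 (adjusted p = 0.672 for each).

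Dopamine neuron markers fell as a list. Of 27 tested members, 26 were below Ctrl, with a median log2 fold change of -0.37 and a mean of -0.38 (camera adjusted p = 2.44e-09, adjusted p = 0.241 with an estimated correlation). Tyrosine hydroxylase (Th, ENSMUSG00000000214, chromosome 7, 142892752 to 142931128), the rate-limiting enzyme of dopamine synthesis, was at 62.4 ± 6.49 CPM in MPTP and 87.0 ± 19.9 CPM in Ctrl (log2 fold change -0.48, SE 0.225, adjusted p = 0.913). The dopamine transporter gene Slc6a3 (chromosome 13, 73536747 to 73578672) was at 112 ± 17.1 and 157 ± 26.2 CPM (adjusted p = 0.913). Ddc was at 85.3 ± 17.0 and 112 ± 12.7 CPM, and the vesicular monoamine transporter gene Slc18a2 at 91.3 ± 19.6 and 113 ± 9.13 CPM (adjusted p = 0.904 and 0.922). No member passed over all genes, and adjusted over the list alone 2 were lower, the nicotinic receptor gene Chrna6 (18.8 ± 1.09 against 27.3 ± 4.30 CPM) and Sncg (21.5 ± 0.944 against 26.4 ± 1.47 CPM). The mean score of the list was -0.61, -0.19 and -0.37 in the MPTP libraries and 0.086, -0.081 and -0.0049 in the Ctrl libraries, a difference with an exact two-sided permutation p of 0.1, the smallest that 3 libraries against 3 allow. Without MPTP 1 the median was -0.24 (camera adjusted p = 5.08e-06), and with Ctrl 3 and MPTP 1 both left out it was -0.22.

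**Figure D1:**
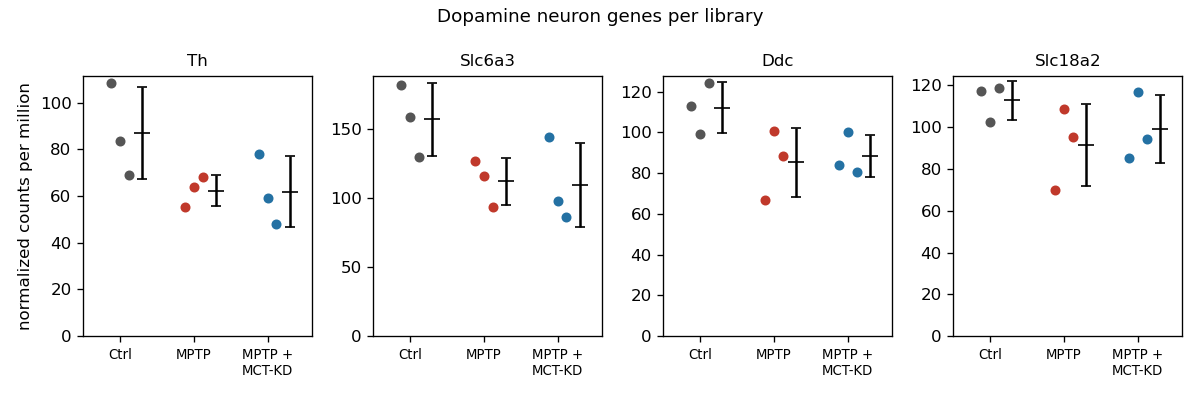
Expression of Th, Slc6a3, Ddc and Slc18a2 in CPM, counts per M counts (vertical axis) by group (horizontal axis), with dots for single libraries and bars for the mean ± SD of 3 libraries. Th averaged 87.0 CPM in Ctrl, 62.4 CPM in MPTP and 61.9 CPM in the diet group, and none of the 4 genes passed the test on its own.

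Stress response genes fell as lists. All 12 tested members of the heat-shock list were below Ctrl, with a median of -0.11 and a mean of -0.34 (camera adjusted p = 1.76e-07, adjusted p = 0.241 with an estimated correlation). Over all genes 2 members passed, and adjusted over the list alone 5 were lower (Dnajb1, Hspa1b, Hspb1, Hspa1a and Dnaja1). Of 24 immediate early genes, which are induced within minutes of neuronal activity or stress, 18 were below Ctrl, with a median of -0.28 (camera adjusted p = 1.67e-05, adjusted p = 0.241 with an estimated correlation). None passed over all genes, and adjusted over the list alone 5 were lower (Fos, Nr4a1, Sik1, Nr4a3 and Klf2). Nr4a1 was at 11.4 ± 0.826 CPM in MPTP and 16.6 ± 2.55 CPM in Ctrl. Of 24 genes of the integrated stress and unfolded protein responses, 18 were below Ctrl, with a median of -0.083 (camera adjusted p = 0.00179, adjusted p = 0.536 with an estimated correlation). Over all genes none passed, and adjusted over the list alone 7 were lower (Hspa5, Xbp1, Manf, Herpud1, Pdia4, Dnajb11 and Ddit4). Xbp1 was at 83.1 ± 1.99 CPM in MPTP and 102 ± 8.20 CPM in Ctrl, and Manf at 37.2 ± 3.17 and 47.7 ± 0.843 CPM. By fry, which asks whether a list's own genes change, the changes in either direction passed for heat shock (adjusted p = 0.000614), immediate early (0.00407) and integrated stress genes (0.00407), and no list passed in a shared direction. Without MPTP 1 the heat-shock median was -0.17, and with Ctrl 3 and MPTP 1 both left out the heat-shock and immediate early medians were -0.21 and -0.16. The immediate early median was -0.15 with the meningeal score as a covariate and also with a pseudocount of 1 in limma. With limma array weights the medians of the dopamine, heat-shock, integrated stress and glucocorticoid lists were -0.24, -0.18, -0.051 and -0.18.

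**Figure D2:**
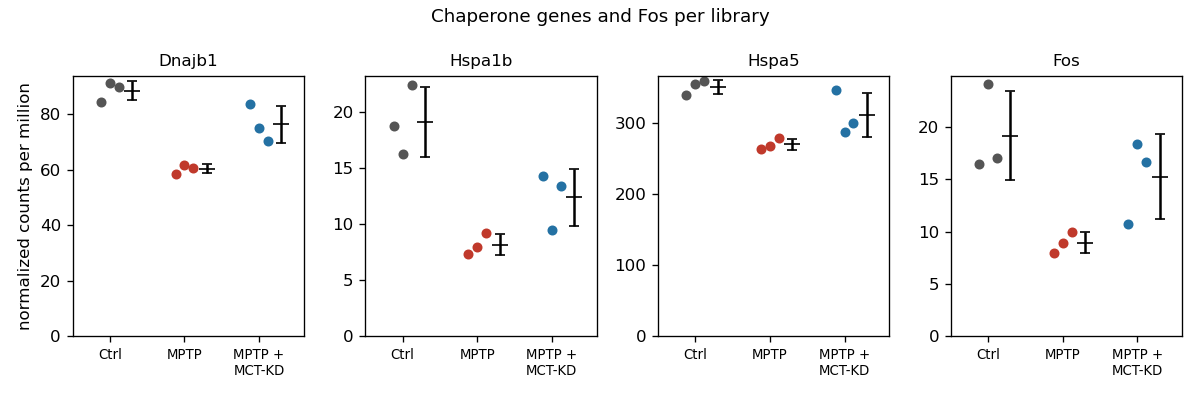
Expression of Dnajb1, Hspa1b, Hspa5 and Fos in CPM, counts per M counts (vertical axis) by group (horizontal axis), with dots for single libraries and bars for the mean ± SD of 3 libraries. Dnajb1 and Hspa1b passed the test between MPTP and Ctrl, with Dnajb1 at 60.3 and 88.4 CPM, while Hspa5 and Fos did not.

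Glial markers split. Of 17 oligodendrocyte genes, 16 were above Ctrl, with a median of 0.18 (camera adjusted p = 7.21e-06, adjusted p = 0.654 with an estimated correlation) and no member past the threshold over all genes or adjusted over the list alone. The myelin enzyme gene Cnp was at 513 ± 40.5 CPM in MPTP and 446 ± 40.7 CPM in Ctrl, and Mag at 328 ± 32.0 and 278 ± 26.6 CPM. The oligodendrocyte median was 0.11 without MPTP 1 and 0.11 without MPTP 2, and with Ctrl 3 and MPTP 1 both left out the call was lost (0.11, camera adjusted p = 0.0520). With the choroid plexus score as a covariate it was also 0.11. Microglial homeostatic genes rose by a median of 0.12, with 12 of 16 above Ctrl (camera adjusted p = 0.0124, adjusted p = 0.640 with an estimated correlation). That call was lost without Ctrl 1 (0.078, adjusted p = 0.184), Ctrl 3 (0.074, adjusted p = 0.0768) or MPTP 1 (0.098, adjusted p = 0.0944), and the median was 0.20 without Ctrl 2. It was also lost with the choroid plexus score as a covariate (0.048, adjusted p = 0.186). Reactive astrocyte genes fell by a median of 0.11 (camera adjusted p = 0.0222, adjusted p = 0.670 with an estimated correlation), and adjusted over the list alone 1 of 20 was lower, Hspb1, which the heat-shock list also holds. The call was lost without Ctrl 1 (-0.037, adjusted p = 0.310) or MPTP 1 (-0.051, adjusted p = 0.555), and the median was -0.071 without MPTP 2 and -0.18 without MPTP 3. It was lost too with the meningeal score (0.0021, adjusted p = 0.998) or the serotonin neuron score (-0.11, adjusted p = 0.155) as a covariate and with no filter on low values (-0.11, adjusted p = 0.124). Gfap itself, the intermediate filament of reactive astrocytes, was at 196 ± 26.4 CPM in MPTP and 169 ± 30.9 CPM in Ctrl (adjusted p = 0.946). The microglial gene Aif1 was at 2.40 ± 0.596 and 2.58 ± 0.927 CPM (adjusted p = 0.985).

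Lists that mark tissue around the nigra, vessels and hormone exposure had medians that moved with single libraries. The choroid plexus call was lost without Ctrl 3 and the glucocorticoid call without Ctrl 1. The red cell and mural calls were kept in the removals of a single library given here. The 8 choroid plexus genes were all below Ctrl, with a median of -2.41 (camera adjusted p = 0.00320, adjusted p = 0.670 with an estimated correlation), and without Ctrl 3 the median was 0.011 (adjusted p = 0.533). On log2 FPKM in limma it lay between -1.37 and -0.94. Haemoglobin and red cell genes, whose copies share reads, fell by a median of 0.65 (camera adjusted p = 0.000112, adjusted p = 0.608 with an estimated correlation), and the median was -0.36 without Ctrl 3 (adjusted p = 0.00269) and -0.33 with the choroid plexus score as a covariate. With no filter on low values the red cell call was lost (-0.59, adjusted p = 0.248). Mural cell and fibroblast genes fell by a median of 0.51, with Acta2 at 16.9 ± 2.08 CPM in MPTP and 29.4 ± 6.17 CPM in Ctrl (camera adjusted p = 0.00179, adjusted p = 0.670 with an estimated correlation). Their median was -0.32 without Ctrl 1, -0.30 without MPTP 1, -0.90 without MPTP 3 and -0.11 with the meningeal score as a covariate. Glucocorticoid response genes fell by a median of 0.29 (camera adjusted p = 0.00320, adjusted p = 0.671 with an estimated correlation). The glucocorticoid call was lost without Ctrl 1 (-0.039, adjusted p = 0.551) and with the meningeal score as a covariate (-0.064, adjusted p = 0.578), and the median was -0.46 without Ctrl 2, -0.45 without Ctrl 3 and -0.48 with the choroid plexus score as a covariate. In none of these 4 lists did a member pass over all genes or adjusted over the list alone.

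Thalamic markers rose by a median of 0.36, with 8 of 9 above Ctrl (camera adjusted p = 0.0201, adjusted p = 0.670 with an estimated correlation), and Ramp3 was at 53.4 ± 16.4 CPM in MPTP and 35.9 ± 7.58 CPM in Ctrl. The thalamic call was lost without Ctrl 2 (0.27, adjusted p = 0.223), Ctrl 3 (0.32, adjusted p = 0.0711), MPTP 1 (0.16, adjusted p = 0.292) or MPTP 2 (0.39, adjusted p = 0.0550), and with the meningeal score as a covariate (0.20, adjusted p = 0.338). Cytosolic ribosomal protein genes fell by a median of 0.036, with 48 of 65 below Ctrl (camera adjusted p = 0.0219, adjusted p = 0.811 with an estimated correlation). The ribosomal call was lost without Ctrl 2 (-0.028, adjusted p = 0.223) or MPTP 3 (0.0027, adjusted p = 0.910). No member of either list passed over all genes or adjusted over the list alone. With Ctrl 3 and MPTP 1 both left out the microglial, thalamic, reactive astrocyte and choroid plexus calls were lost (adjusted p = 0.381, 0.494, 0.294 and 0.990), and the red cell median was -0.20.

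Other neurons and the metabolic pathways named in the design did not pass. GABA neuron markers had a median of -0.058 (adjusted p = 0.401), with Gad2 at 362 ± 5.58 CPM in MPTP and 383 ± 36.2 CPM in Ctrl. Nuclear genes of complex I, the target of the toxin, had a median of -0.042, with 29 of 37 below Ctrl (adjusted p = 0.105). Inflammation genes had a median of -0.015 (adjusted p = 0.960) and interferon genes -0.037 (adjusted p = 0.492). Ketone metabolism genes had a median of 0.017 and a mean of 0.026 while the test pointed down (adjusted p = 0.960), and Bdh1 and Oxct1 had log2 fold changes of -0.053 and 0.061. Genes linked to inherited Parkinson's disease had a median of -0.018 and a mean of 0.0018 (adjusted p = 0.812). Median, mean and test also differed in sign for the fatty acid oxidation, glycolysis, antioxidant, autophagy, hypothalamic and mitochondrially encoded lists, none of which passed. Adjusted over the list alone, Prox1 was higher in the cortical and hippocampal list (median 0.051, adjusted p = 0.207) and Manf lower in the neurotrophic list (median -0.041, adjusted p = 0.241).

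The comparison of the diet group with MPTP addressed what the diet changed in mice given the toxin. Glucocorticoid response genes rose as a list, all 17 lying above MPTP with a median 44.0% higher (adjusted p = 0.857 with an estimated correlation), although the lowest list score of a diet library, -0.191, lay below the highest MPTP score, -0.168. Immediate early genes rose by a median of 14.9% (adjusted p = 0.459 with an estimated correlation). Nuclear genes of the mitochondrial respiratory chain rose by medians of 4.74% for complex I and 4.93% for the other complexes, and genes of cholesterol synthesis fell by a median of 4.77% (adjusted p = 0.857 with an estimated correlation for each of these 3 lists). Dopamine neuron markers did not pass: Th was at 61.9 ± 15.2 CPM with the diet and 62.4 ± 6.49 CPM without it (SD, n = 3).

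No gene passed by edgeR's quasi-likelihood test, where 562 genes were higher and 601 lower at an unadjusted p under 0.05 and the smallest adjusted p was 0.469. DESeq2 called 19 genes, and limma on log2 FPKM called 0, with 1171 under an unadjusted p of 0.05. Expression did not overlap between the groups for 2053 genes (13.7%, where chance gives 10%). Without MPTP 1 edgeR called 1 gene, the histone gene Hist2h2aa2, and without MPTP 2 it called 1, Fsd1l, both higher with the diet and both named after their values were seen.

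The genes of smallest p are given as values, each with an adjusted p of 0.469 or 0.550. The transcription elongation inhibitor gene Hexim1 was at 81.7 ± 1.83 CPM with the diet and 66.0 ± 3.86 CPM in MPTP. Dnajb1 was at 76.3 ± 6.59 and 60.3 ± 1.67 CPM (log2 fold change 0.34, SE 0.0653). The growth factor receptor inhibitor gene Errfi1 was at 49.4 ± 2.61 and 37.7 ± 2.45 CPM, and the phosphatase gene Dusp1 at 25.2 ± 3.26 and 16.9 ± 0.900 CPM. Tinagl1, Pcna, Wipf3, Mbd2, Slmap and Mkks had log2 fold changes of 0.65, 0.36, 0.48, 0.30, 0.20 and 0.34. On the lower side, fatty acid synthase (Fasn, ENSMUSG00000025153, chromosome 11, 120805846 to 120824547) was at 342 ± 6.97 CPM with the diet and 402 ± 16.8 CPM in MPTP (log2 fold change -0.23, SE 0.0443). The taurine transporter gene Slc6a6 was at 114 ± 2.12 and 136 ± 2.02 CPM. Celsr3, Epha8, Cabin1, Gtpbp6, Alk, Dpysl5 and Dalrd3 had log2 fold changes of -0.34, -0.44, -0.25, -0.42, -0.44, -0.29 and -0.25.

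Glucocorticoid response genes had a median log2 fold change of 0.53 (camera adjusted p = 2.59e-07, adjusted p = 0.857 with an estimated correlation). No member passed over all genes, while adjusted over the list alone 2 were higher, Errfi1 and Tsc22d3 (131 ± 16.5 CPM with the diet against 97.5 ± 6.64 CPM). Cdkn1a was at 19.6 ± 5.51 and 11.1 ± 0.477 CPM, and Pdk4, which restrains glucose oxidation, at 15.6 ± 5.32 and 10.8 ± 1.59 CPM. The list score was 0.59 and 0.43 in diet libraries 2 and 3 and -0.19 in diet library 1, which also had the low meningeal score. Among the controls it was 0.49 in Ctrl 1, -0.20 in Ctrl 2 and -0.28 in Ctrl 3, so a score as high also occurred in a control library. With the meningeal score as a covariate the median of the diet group against MPTP was 0.25 (camera adjusted p = 0.000255). Mural cell and fibroblast genes rose by a median of 0.68, with Acta2 at 31.0 ± 10.2 CPM with the diet (camera adjusted p = 0.00910, adjusted p = 0.857 with an estimated correlation). No mural member passed over all genes or adjusted over the list alone, where 7 passed with the replicate number as a block in MPTP and the diet group only. With the number as a block in all groups 1 glucocorticoid gene passed adjusted over the list alone, Errfi1. The mural call was lost without MPTP 1 (0.47, adjusted p = 0.133), MPTP 2 (0.51, adjusted p = 0.0909), diet library 2 (0.60, adjusted p = 0.0692) or diet library 3 (0.37, adjusted p = 0.286), and with Ctrl 3 and MPTP 1 both left out (0.47, adjusted p = 0.104), and the median was 0.16 with the meningeal score as a covariate.

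Of 24 immediate early genes, 20 lay above MPTP, with a median of 0.20 (camera adjusted p = 2.58e-05, adjusted p = 0.459 with an estimated correlation). None passed over all genes, and adjusted over the list alone 5 were higher (Dusp1, Nr4a3, Egr3, Nr4a1 and Fos). With the replicate number as a block 6 passed on that adjustment in all groups, Klf4 being added, and 7 in MPTP and the diet group only, Klf4 and Fosl2 being added. Egr3 was at 6.58 ± 2.94 CPM with the diet and 3.15 ± 0.465 CPM in MPTP. The transcript length implied by its count and FPKM differed 1.6-fold between libraries. Heat-shock genes rose by a median of 0.096, with 10 of 12 above MPTP (camera adjusted p = 0.00978, adjusted p = 0.857 with an estimated correlation). Over all genes none passed, and adjusted over the list alone 4 were higher (Dnajb1, Hspa1b, Hspb1 and Dnaja1), and 5 passed with either block, Bag3 being added. Hspa1b was at 12.4 ± 2.54 and 8.17 ± 0.965 CPM. The heat-shock call was lost without MPTP 3 (0.041, adjusted p = 0.0703) or diet library 1 (0.061, adjusted p = 0.144), and the median was 0.17 with the meningeal score as a covariate. By fry, the changes in either direction passed for immediate early (adjusted p = 0.00496) and heat-shock genes (0.00442). They also passed for the integrated stress, fatty acid synthesis and neurotrophic lists (0.0395 for each), none of which camera called (adjusted p = 0.0713, 0.261 and 0.931). With the replicate number as a block the fatty acid synthesis and neurotrophic lists did not pass by fry, whether in all groups (adjusted p = 0.529 and 0.0636) or in MPTP and the diet group only (0.0506 and 0.0645), and the cholesterol synthesis list did in the latter (0.0299). Adjusted over the list alone 1 fatty acid synthesis gene was lower, Fasn, with a list median of -0.054.

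Nuclear genes of complex I rose by a median of 0.067, with 34 of 37 above MPTP (camera adjusted p = 2.52e-05, adjusted p = 0.857 with an estimated correlation), and Ndufb2 was at 60.1 ± 0.776 CPM with the diet and 53 ± 1.24 CPM in MPTP. For Ndufb2 the transcript length implied by count and FPKM differed 1.3-fold between libraries. Nuclear genes of the other respiratory complexes and of ATP synthase rose by a median of 0.070, with 34 of 38 above MPTP (camera adjusted p = 0.000247, adjusted p = 0.857 with an estimated correlation), and Cox7c was at 62.0 ± 1.01 and 52.6 ± 6.25 CPM. No member of either list passed over all genes or adjusted over the list alone. Without MPTP 3 both calls were lost, at medians of 0.029 (adjusted p = 0.0601) and 0.038 (adjusted p = 0.321). The medians were 0.13 and 0.13 without MPTP 1, with or without Ctrl 3, and 0.10 and 0.11 without diet library 3. With the meningeal score as a covariate the complex I median was 0.10. Genes of cholesterol synthesis fell by a median of 0.071, with 17 of 23 below MPTP (camera adjusted p = 0.00289, adjusted p = 0.857 with an estimated correlation). No member passed over all genes, while adjusted over the list alone 1 was lower. Fdft1, which makes squalene, had a log2 fold change of -0.17 (adjusted p = 0.625). The cholesterol call was lost without diet library 1 (-0.067, adjusted p = 0.0646) or diet library 3 (-0.067, adjusted p = 0.0627), and the median was -0.12 without MPTP 1, with or without Ctrl 3, and -0.11 without diet library 2.

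Dopamine neuron markers had a median of -0.0061 between the diet group and MPTP, with 13 members above and 14 below, a mean of 0.023 and a test that pointed up (camera adjusted p = 0.931, exact two-sided permutation p of the score 0.8). Slc6a3 was at 109 ± 30.4 CPM with the diet and 112 ± 17.1 CPM in MPTP, Ddc at 88.2 ± 10.3 and 85.3 ± 17.0 CPM, and Slc18a2 at 98.9 ± 16.3 and 91.3 ± 19.6 CPM. Genes of ketone use did not pass (median -0.075, adjusted p = 0.460). Among them Bdh1 and Oxct1 had log2 fold changes of -0.016 and 0.070. Fatty acid oxidation (median 0.020, adjusted p = 0.296), inflammation (0.043, adjusted p = 0.639) and reactive astrocyte genes (0.20, adjusted p = 0.0713) did not pass either. With the replicate number as a block in all groups the reactive astrocyte list passed (0.20, camera adjusted p = 0.0226, adjusted p = 0.859 with an estimated correlation). With the block in MPTP and the diet group only, a setting chosen after seeing the data, it passed too (0.20, camera adjusted p = 0.00775, adjusted p = 0.601 with an estimated correlation). In that setting the complement and MHC list also passed (0.11, camera adjusted p = 0.0101, adjusted p = 0.601 with an estimated correlation), where without a block its adjusted p was 0.0614. By fry both lists passed there in either direction (adjusted p = 0.000172 and 0.0462), and the reactive astrocyte list did with the block in all groups (adjusted p = 0.0039). Adjusted over the list alone, 2 reactive astrocyte genes passed with either block, Hspb1 with Gfap or with Serping1, and so did 2 oligodendrocyte genes in the first (Mobp and Ermn) and 1 neurotrophic gene in the second (Manf). Gfap was at 267 ± 41.7 CPM with the diet and 196 ± 26.4 CPM in MPTP (adjusted p = 0.630), and Aif1 at 2.23 ± 0.326 and 2.40 ± 0.596 CPM. Median, mean and test also differed in sign for the glutamate neuron, oligodendrocyte precursor, neurotrophic and synapse lists, none of which passed.

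**Figure D3:**
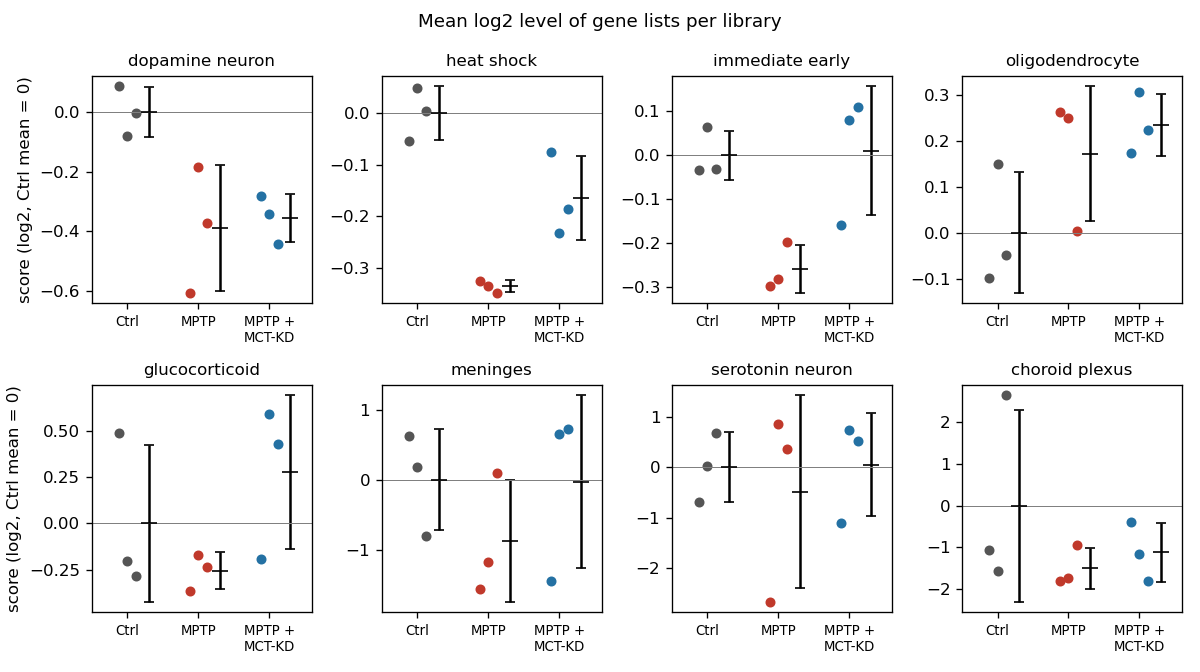
Mean log2 level of 8 gene lists (vertical axis, log2 units with the Ctrl mean at 0) by group (horizontal axis), with dots for single libraries and bars for the mean ± SD of 3 libraries. The dopamine neuron score lay at -0.19 or lower in all 6 libraries from mice given MPTP, and the choroid plexus score reached 2.64 in Ctrl 3.

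The comparison of the diet group with Ctrl gave the joint difference of MPTP and the diet. Dopamine neuron markers fell as a list by a median of 20.5%, with all 27 members below Ctrl. Myelin genes rose by a median of 18.4%, with all 17 above Ctrl, and microglial homeostatic genes by 11.9%. Genes of cholesterol synthesis fell by a median of 6.90%, with 19 of 23 below Ctrl. For each of these 4 lists the adjusted p was 0.721 with an estimated correlation.

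No gene passed by edgeR's quasi-likelihood test, with 503 genes higher and 503 lower at an unadjusted p under 0.05. DESeq2 called 14 genes, and limma on log2 FPKM called 0, with 1003 under an unadjusted p of 0.05. Expression did not overlap between the groups for 1895 genes (12.7%, where chance gives 10%). The smallest adjusted p belonged to the vascular growth factor gene Vegfa (ENSMUSG00000023951, chromosome 17, 46016993 to 46032369), at 65.7 ± 0.772 CPM with the diet and 88.0 ± 3.16 CPM in Ctrl (log2 fold change -0.42, SE 0.0582, adjusted p = 0.0823). With no filter on low values Vegfa passed (adjusted p = 0.0148). Without MPTP 3 edgeR called 4 genes, among them Vegfa and Mrps34, without MPTP 2 it called 1, Mrps34, and without diet library 1 it called 1, Iqschfp, named after its values were seen. Mrps34, a mitochondrial ribosomal protein gene, was at 25.4 ± 1.25 CPM with the diet and 44.3 ± 3.76 CPM in Ctrl (adjusted p = 0.242), and the transcript length implied by its count and FPKM differed 1.43-fold between libraries. Fasn was at 342 ± 6.97 and 394 ± 4.47 CPM (adjusted p = 0.706). Utp14b, Atg9b, Ldha and Fdps had log2 fold changes of -0.49, -0.59, -0.22 and -0.29. On the higher side Olfm1 and Rnf141 had log2 fold changes of 0.25 and 0.28 (adjusted p = 0.5 for both), Rnf26 0.60 (adjusted p = 0.562), and Trak2, Gpm6b, Wipf3, Fzd6 and P2ry12 0.29, 0.21, 0.49, 0.45 and 0.41 (adjusted p = 0.740 for each).

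The dopamine list had a median log2 fold change of -0.33 (camera adjusted p = 7.43e-09, adjusted p = 0.721 with an estimated correlation, exact two-sided permutation p of the score 0.1). No member passed over all genes or adjusted over the list alone. Th was at 61.9 ± 15.2 CPM with the diet and 87.0 ± 19.9 CPM in Ctrl, and Slc6a3 at 109 ± 30.4 and 157 ± 26.2 CPM (adjusted p = 0.753 for both). Slc10a4 and Nr4a2 had log2 fold changes of -0.45 and -0.38. The oligodendrocyte list had a median of 0.24 (camera adjusted p = 1.94e-09, adjusted p = 0.721 with an estimated correlation). None of its members passed over all genes, and adjusted over the list alone 4 were higher (Cldn11, Cnp, Mobp and Mal). Mobp was at 2320 ± 85.4 CPM with the diet and 1850 ± 149 CPM in Ctrl, and Cldn11 at 208 ± 11.3 and 164 ± 9.94 CPM. Microglial genes had a median of 0.16 (camera adjusted p = 0.00146, adjusted p = 0.721 with an estimated correlation). None passed over all genes, and adjusted over the list alone 1 was higher, the purinergic receptor gene P2ry12 (21.1 ± 1.14 against 15.9 ± 0.578 CPM). Cholesterol synthesis had a median of -0.10 (camera adjusted p = 6.83e-06, adjusted p = 0.721 with an estimated correlation). Over all genes none passed, and adjusted over the list alone 4 were lower, among them Fdps and Fdft1. Fdps was at 42.2 ± 2.28 CPM with the diet and 51.5 ± 3.06 CPM in Ctrl.

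The remaining lists that passed lost their call without 1 or more libraries. Heat-shock genes fell by a median of 0.061, with 10 of 12 below Ctrl (camera adjusted p = 0.00687, adjusted p = 0.721 with an estimated correlation), and adjusted over the list alone 2 were lower, Hspa1b and Dnajb1, with none over all genes. Without Ctrl 2 the heat-shock call was lost (-0.056, adjusted p = 0.0630), and the median was -0.091 without Ctrl 3 and -0.11 without diet library 1. It was -0.10 in limma on log2 FPKM with each of 3 pseudocounts or array weights, -0.11 with quantile scaling and -0.093 with Ctrl 3 and MPTP 1 both left out. Complex I genes rose by a median of 0.033 and genes of the other complexes by 0.039 (camera adjusted p = 0.00769 for both, adjusted p = 0.796 with an estimated correlation). The complex I call was lost without Ctrl 1, Ctrl 3 or diet library 1 (adjusted p = 0.0851, 0.171 and 0.114), and that of the other complexes without Ctrl 1, Ctrl 3, diet library 1 or diet library 2 (adjusted p = 0.0851, 0.141, 0.0796 and 0.0733). Without Ctrl 2 these medians were 0.072 and 0.075, and without diet library 3 they were 0.059 and 0.065. In limma on log2 FPKM with other pseudocounts or quantile scaling they were 0.013 to 0.016 and 0.021 to 0.022, and with array weights the complex I median was 0.0195. Glucocorticoid response genes rose by a median of 0.21 (camera adjusted p = 0.00840, adjusted p = 0.796 with an estimated correlation). This call was lost without Ctrl 2, Ctrl 3, diet library 2 or diet library 3 (adjusted p = 0.136, 0.379, 0.397 and 0.133), and the median was 0.42 without Ctrl 1 and 0.46 without diet library 1. No member of these 3 lists passed over all genes or adjusted over the list alone.

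Markers of other tissue followed single libraries here too. The choroid plexus list had a median of -1.87 (camera adjusted p = 0.0314, adjusted p = 0.796 with an estimated correlation), which turned to 0.21 without Ctrl 3 (adjusted p = 0.754) and was not called without diet library 2 or 3 (adjusted p = 0.0701 and 0.212), with a pseudocount of 0.1 in limma (-0.96, adjusted p = 0.0678) or with only the 6 libraries compared (-1.86, adjusted p = 0.0655). In limma its median lay between -1.09 and -0.76. Red cell genes fell by a median of 0.54 (camera adjusted p = 0.00947, adjusted p = 0.796 with an estimated correlation), and without Ctrl 3 the median was -0.26 (adjusted p = 0.260). With no filter on low values the red cell call was lost (-0.35, adjusted p = 0.560), and with a pseudocount of 1 in limma the median was -0.36. Cortical and hippocampal markers rose by a median of 0.32 (camera adjusted p = 0.0149, adjusted p = 0.721 with an estimated correlation). Adjusted over the list alone 1 of its 8 members was higher, the glutamate transporter gene Slc17a7, at 165 ± 43.7 CPM with the diet and 80.4 ± 13 CPM in Ctrl. Its call was lost without Ctrl 1 (0.32, adjusted p = 0.0717), Ctrl 3 (0.23, adjusted p = 0.0628) or diet library 3 (0.18, adjusted p = 0.212), and with no filter on low values the median was 0.70. Thalamic markers rose by a median of 0.38 (camera adjusted p = 0.0314, adjusted p = 0.796 with an estimated correlation), a call lost without Ctrl 2 (0.25, adjusted p = 0.307), Ctrl 3 (0.33, adjusted p = 0.141) or diet library 1 (0.10, adjusted p = 0.375). No member of the choroid plexus, red cell or thalamic lists passed over all genes or adjusted over the list alone, and no cortical member passed over all genes. The cortical, thalamic, red cell and glucocorticoid calls were lost too with the choroid plexus score as a covariate (adjusted p = 0.0621, 0.0654, 0.114 and 0.260), and so were those of complex I and of the other complexes (0.132 and 0.122). With Ctrl 3 and MPTP 1 both left out these 6 calls were lost as well, with adjusted p-values from 0.0537 to 0.393. Quantile scaling ended the complex I call (adjusted p = 0.117).

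The remaining lists did not pass. Immediate early genes had a median of 0.0039, with 12 above and 12 below Ctrl (adjusted p = 0.918). Ketone metabolism genes had a median of -0.055 (adjusted p = 0.397), and Bdh1 and Oxct1 had log2 fold changes of -0.069 and 0.13. Gfap was at 267 ± 41.7 CPM with the diet and 169 ± 30.9 CPM in Ctrl (adjusted p = 0.740), and Ddc and Slc18a2 had log2 fold changes of -0.35 and -0.19. By fry, the changes in either direction passed for the striatal list (adjusted p = 0.000298), where adjusted over the list alone 1 gene was higher, the phosphodiesterase gene Pde10a (log2 fold change 0.27), and for the microglial list (0.0188). Median, mean and test differed in sign for the GABA neuron, striatal, mural, interferon, reactive astrocyte, p53, activated microglia and glycolysis lists.

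Whether the diet group lay nearer to Ctrl than MPTP did was compared gene by gene. Both genes called in MPTP lay nearer to Ctrl with the diet: Dnajb1 had log2 fold changes of -0.55 in MPTP and -0.21 in the diet group against Ctrl, and Hspa1b had -1.23 and -0.63. Selection for a low value in MPTP favours this without any effect of the diet. Of 402 genes lower in MPTP at an unadjusted p under 0.05, 362 (90%) lay nearer to Ctrl with the diet, against a mean of 90.7% (87.2% to 94.4%) in 50 simulations with no difference between the groups. Over all genes the share was 48%, below the simulated range of 49.3% to 50.9% (mean 50.1%). Genes that vary together may widen such a range beyond the simulated one, so the 48% is not read as a departure from no difference. Among the 10 lists lower in MPTP, those nearer to Ctrl were 13 of 27 dopamine neuron, 10 of 12 heat-shock, 18 of 24 immediate early and 17 of 24 integrated stress genes. They were 15 of 17 mural cell, 5 of 5 red cell, 6 of 8 choroid plexus, 7 of 20 reactive astrocyte, 9 of 17 glucocorticoid response and 40 of 65 ribosomal protein genes. These lists were selected for low values in MPTP too, so their counts do not show an effect of the diet. No gene was called in opposite directions in MPTP against Ctrl and in the diet group against MPTP by edgeR, where independent lists would also share 0 and where 223 genes had fold changes of opposite sign and 4 of the same sign at an unadjusted p under 0.05 in both. DESeq2 called 3 genes in opposite directions and limma 0, and without MPTP 1 or MPTP 2 edgeR called 1. The fold changes of these comparisons share the MPTP libraries, which makes them negatively correlated without any effect. Their correlation across genes was -0.503, against a mean of -0.511 (-0.640 to -0.410) in 50 simulations with no difference between the groups. Their covariance was -0.0406, against a simulated mean of -0.0361 (-0.0537 to -0.0268). The 3 MPTP libraries could not be split into parts of at least 2 libraries each, so part of any excess may come from the shared libraries.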

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

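DESeq2, limma on log2 FPKM, the removal of both Ctrl 3 and MPTP 1, the block in MPTP and the diet group only and the score covariates were chosen only after the results were seen, and the cause of a change was not tested unless stated. For MPTP against Ctrl, 2 genes became 0 with a pseudocount of 0.1, 0.5 or 1 in limma, quantile scaling, array weights, no robust moderation or the choroid plexus covariate. The number was 1 with the meningeal or the serotonin covariate (Dnajb1), an absolute log2 fold change of at least 1 (Hspa1b) or both libraries left out (neither of the 2 but Hist2h2aa2, chosen after its values were seen). It was 14 with DESeq2, and leaving out 1 library gave 0 to 4. For the diet group against MPTP, 0 genes became 19 with DESeq2 and 1 with both libraries left out, and leaving out 1 library gave 0 to 1. Against Ctrl, the diet group's 0 became 14 with DESeq2, 4 with only the 6 libraries compared, 2 with the serotonin covariate and 1 with no filter or an adjusted p under 0.1, and leaving out 1 library gave 0 to 4. Genes called in opposite directions went from 0 to 3 with DESeq2 and 1 with both libraries left out, and leaving out 1 library gave 0 to 1.

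Lists past the threshold, 13, 7 and 12 in the 3 comparisons, became 0 in each with camera's estimated correlation and 0 with fry, which allow the members of a list to vary together. For the diet group against MPTP they became 11 with both libraries left out or the choroid plexus covariate, and 5 to 11 leaving out 1 library. In the diet group against Ctrl they became 5 in both of these settings, and 5 to 13 leaving out 1 library. The dopamine median of -0.371 was no longer past the threshold with an estimated correlation (adjusted p = 0.241) or fry (adjusted p = 0.154). It ranged from -0.465 to -0.236 leaving out 1 library and was -0.217 with both left out. The choroid plexus median turned sign in the diet group against Ctrl without Ctrl 3 (0.21, against -2.33 without Ctrl 2, the other end of the range), with both libraries left out (0.21) and with its own score as a covariate (0.097). In MPTP against Ctrl it turned sign without Ctrl 3 (0.011), with both libraries left out (0.11) and with that covariate (0.099). The covariate removes the list's own signal.

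With the replicate number as a block, 3, 0 and 5 genes were called in the 3 comparisons and the dopamine median of MPTP against Ctrl, from the list of dopamine neuron markers, was -0.35. With the block in MPTP and the diet group only, 3, 0 and 4 genes were called, and the choroid plexus call of the diet group against Ctrl was lost (adjusted p = 0.0848), while with the block in all groups that median was -1.06 (adjusted p = 0.0236). For the diet group against MPTP, whose same-numbered libraries met the minimum for pairing, camera's calls changed for no fixed list other than the reactive astrocyte and complement lists. As a hint from the data, 5 of 9 libraries had their highest correlation with a library of their own number, and 2 of 9 correlated best with it in both other groups. Among the other values, 8188 kept their side of the threshold, lists with the same direction and genes within the SE of their main value. Another 230 moved further, 165 lost and 55 gained a call, and 4 reversed. These 4 were counted over genes and lists together, for lists by the direction of camera's test and not by the sign of the median. Of 7743 values of named genes 54 changed sign.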

Other observations

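The tests of explanations, the pathway tests and the counts of other splits in this part were chosen after the results were seen.

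Pathways named in the annotation column of the deposited table gave 317 sets over 6557 genes. In the diet group against MPTP, 103 of 129 genes of oxidative phosphorylation lay higher, with a median log2 fold change of 0.058 (camera adjusted p = 0.000165, adjusted p = 0.798 with an estimated correlation). Of 49 genes of aminoacyl-tRNA biosynthesis, which charge transfer RNAs with amino acids, 39 lay lower with the diet, with a median of -0.064 (camera adjusted p = 0.0143, adjusted p = 0.713 with an estimated correlation). In MPTP against Ctrl 39 of these 49 genes lay higher, with a median of 0.061 (camera adjusted p = 0.142). Both comparisons share the MPTP libraries, which favours opposite signs without any effect, so this does not show a reversal by the diet. The pathway sets for non-alcoholic fatty liver disease, Parkinson disease and prion disease also passed in the diet group against MPTP (camera adjusted p = 0.00395, 0.0238 and 0.0238, adjusted p = 0.713, 0.798 and 0.798 with an estimated correlation). Pathway sets can share genes. How far these overlap with oxidative phosphorylation is not given here, so they may not be separate results. The fixed lists of complex I and of the other complexes lost their calls without MPTP 3 (camera adjusted p = 0.0601 and 0.321). In the diet group against Ctrl oxidative phosphorylation passed (median 0.035, adjusted p = 0.0249, adjusted p = 0.958 with an estimated correlation), and in MPTP against Ctrl camera called 0 pathways.

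The gene Fsd1l (ENSMUSG00000054752, chromosome 4, 53631471 to 53707009, GRCm38), chosen after its values were seen, had 219 counts in MPTP 1 and 257 in MPTP 3, against 1382 to 1805 in the other libraries. Its FPKM was 3.82 and 4.63 in those libraries, and the transcript length implied by count and FPKM was 1.60 kb in both, against 7.02 to 7.81 kb elsewhere. Hist2h2aa2 was at 2.14 and 2.19 CPM in MPTP 2 and MPTP 3 and at 7.32 to 10.9 CPM in the other libraries. Of the lists written after the data were seen, 12 meningeal genes had a median of -0.88 in MPTP against Ctrl (camera adjusted p = 0.00674, adjusted p = 0.439 with an estimated correlation), 0.99 in the diet group against MPTP (0.00296, adjusted p = 0.575 with an estimated correlation) and 0.078 in the diet group against Ctrl (0.683). The 7 pineal genes had medians of -3.28, -1.12 and -4.40.

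Heat-shock and immediate early genes were lower in MPTP than in Ctrl. Choroid plexus and pineal tissue in Ctrl 3 is argued against as the whole cause, since with the choroid plexus score as a covariate the heat-shock median was -0.138 (-0.111 without) and the scores of MPTP minus Ctrl differed by -0.328 (SE 0.0563) for heat-shock and -0.294 (SE 0.0906) for immediate early genes. Single genes lost their calls there, Dnajb1 going from -0.55 (SE 0.0652) to -0.52 (SE 0.0747) and Hspa1b from -1.23 (SE 0.167) to -1.07 (SE 0.163), with 1 residual degree of freedom fewer. Reads shared between Hspa1a and Hspa1b are argued against as the whole cause, since without both genes the lowest Ctrl heat-shock score exceeded the highest MPTP score by 0.133 (SDs 0.0548 and 0.0359), against 0.271 with them (SDs 0.0523 and 0.0112). Handling or the time before freezing, which may induce both lists, cannot be told apart from the group (immediate early median -0.275), and an effect of MPTP itself stays open as a hypothesis.

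Dopamine neuron markers were lower in MPTP than in Ctrl. The median was -0.316 without Ctrl 3, which argues against the tissue in that library as the whole cause. It was -0.348 with the serotonin neuron score as a covariate, which argues against a dissection that differed along that axis as the whole cause. A dissection with less nigra and more dorsal tissue may also lower these markers and cannot be told apart from the group, since the thalamic median was 0.357 and rested on single libraries. Loss of dopamine neurons or of their transcripts after MPTP stays open as a hypothesis.

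Glucocorticoid response genes were higher with the diet than in MPTP alone. Whether the diet acted alike in all 3 diet libraries stays open: the list scores of same-numbered libraries differed by 0.173, 0.76 and 0.666 (SD 0.315), and with 3 pairs a sign test gives no p below 0.25. Meningeal tissue in some libraries may carry part of the difference, since the median of 0.526 became 0.246 with the meningeal score as a covariate, and this cannot be told apart from hormone exposure with these libraries. The control library Ctrl 1 scored 0.486, so a high score was not particular to the diet group. An effect of the diet on hormone exposure stays open as a hypothesis.

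With 3 libraries against 3 there are 10 splits of the 6 libraries, too few for a share under 0.05. For MPTP against Ctrl the real split called 2 genes, the highest other also 2, and 2 of the 10 splits called as many. For the diet group against MPTP, where same-numbered libraries met the minimum for pairing, the real split is 1 of 4 that part all 3 pairs. It called 0 genes, as all 4 did (highest other 0). The 6 splits that part 1 pair called up to 16 genes, in the split that set diet library 1, MPTP 1 and MPTP 2 apart, the libraries with low meningeal scores. This points to a structure of the samples other than the groups. Between the diet group and Ctrl the real split called 0 genes, a count that all 10 reached, and the highest other 5. Lists called were 13 against a highest other of 12 (1 split as large), 7 against 12 (2 of the 4 splits as large, and up to 13 lists in the 6 that part 1 pair) and 12 against 15 (3 splits). The dopamine median of -0.371 was set against a highest other of -0.222 (1 split as large). Camera called the dopamine list in mixed splits too. Its adjusted p was 1.43e-06 with MPTP 1, MPTP 3 and Ctrl 3 set apart, and 0.000113 with Ctrl 2 in place of Ctrl 3. Those splits keep MPTP 1 and MPTP 3 together, so part of a group difference may remain in them. A small camera p for this list is therefore not particular to the real groups.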
